A study of Homo sapiens with 9 samples.

How the data were processed

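The series holds 9 RNA sequencing libraries of PaTu 8988t, an established human line grown from a metastasis of a pancreatic adenocarcinoma. Per the labels, the cells met an extracellular matrix of 1 of 3 kinds, with 3 libraries each: a control matrix, a matrix containing wild-type CPXM2 and a matrix containing the CPXM2 mutant R213A. CPXM2 is carboxypeptidase X, M14 family member 2, a secreted protein with a discoidin domain. Per the labels' protocols, RNA was taken up in TRIzol and about 500 ng of total RNA went into each library, made with the Illumina TruSeq stranded mRNA kit. The submitters' processing notes name the genome build hg38 and the base-calling converter bcl2fastq. The aligner, the counting program, the strand setting of the counting and the annotation release are not given in the sources used here, so values of genes with an antisense partner or a near-identical copy elsewhere remain uncertain.

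The deposited values are FPKM, which the authors computed per gene. They were deposited as 2 separate tables with the same 58735 Ensembl genes. The 4-library table holds control 1, wild type 1, R213A 1 and R213A 3, and the 5-library table holds control 2 and 3, wild type 2 and 3 and R213A 2. No source used here says whether the tables mark separate cultures, preparations or sequencing runs. For 58207 gene identifiers a current symbol was taken from a reference table by Ensembl identifier. Multiplying FPKM by the listed gene length gave whole reads for 100% of the values above 0 in each library, within a tolerance of 0.01 reads. The library scaling in the deposited values differed from the recovered read totals by a factor between 0.850 and 1.09, a step whose source is not given. At these depths a gene at 0 reads has an upper limit of 3 reads for counting error only.

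Since FPKM values are not counts, levels were compared on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3, for the 11193 genes with a mean of at least 1 FPKM. Fold changes on this scale understate those of genes with low values. All 9 libraries entered a single fit with a mean-variance trend, with the group and the deposited table as terms, so each difference between groups was formed within tables. A difference could also draw on the third group through the table term, above all in fits that lost the only library of a group in a table. The tables may have been scaled separately, so levels across them are described but no group difference rests on them. The fit left 5 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The median 95% interval of a fold change reached 0.48, 0.50 and 0.50 to either side on the log2 scale in the 3 comparisons (wild type against control, R213A against control, wild type against R213A).

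A set of 42 gene lists with 898 entries was written from textbook knowledge, of which 38 lists had at least 3 members measured. They covered matrix adhesion and mechanical signalling, growth factor pathways, cell cycle, lipid and energy metabolism, stress, tumour cell state, markers of other cell types and transcripts that follow RNA quality. Lists were tested with camera in limma at a preset correlation of 0.01, and again with a correlation estimated from the residuals. The rotation test fry was run beside them: its directional and mixed forms ask whether the genes of a list move on balance, or in either direction, and compare the list with no other genes.

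Named genes followed a rule. Per comparison it took the 10 protein-coding genes with the largest rise and the 10 with the largest fall past the threshold, with the same direction in both tables. Where fewer passed, the 20 places were filled with the genes of smallest unadjusted p under the same condition on direction. It also took up to 4 members of smallest p per list, and 14 fixed genes of the matrix and of adhesion. The text names a part of these, chosen for a known function after the values were seen, and genes on unplaced scaffolds are not named because of possible near-identical copies. The design, the lists, the naming rule and most alternatives were set before the data were examined. The alternatives changed the pseudocount (0.1 and 0.5), the filter (none, or a mean of at least 5 FPKM), the scaling (quantile, median of ratios), the table term, the replicate number as a block, the libraries in the fit, the spread model and each library in turn. Alternatives chosen after seeing the data were limma-voom on the recovered reads, a correction for gene length and GC content by splines with 5 degrees of freedom, the list tests within each table, the list tests without the trend or with library weights, and the 5-library table without control 2.

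The procedure was tested on simulated data made from the measured means and spread, with 200 of 11193 genes changed. The simulated spread of a gene was equal in all 9 libraries and independent between genes. The measured libraries were unequal in spread, so the shares below hold for the simulated setting and may not hold for these data. For wild type against control it recovered 59% of the genes changed 2-fold and 99% of those changed 4-fold, with 15 false calls. The shares were 43% and 99% with 13 false calls for R213A against control, and 44% and 98% with 6 false calls for wild type against R213A. Nothing was left out: all 9 libraries entered the fit, and no columns of other samples were found.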

Results

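The study asked how a collagen matrix aligned by CPXM2 affects gene expression and signalling in pancreatic tumour cells. RNA was sequenced from PaTu 8988t cells on a control matrix, on a matrix containing wild-type CPXM2 and on a matrix containing the R213A mutant, with 3 libraries per group. Recovered totals were 17160420, 18211216 and 17434029 reads for control 1 to 3, 18203911, 18301882 and 18312806 for wild type 1 to 3, and 15951927, 16879407 and 18129181 for R213A 1 to 3. Between 20059 and 21401 genes had at least 1 read, and mitochondrial transcripts took 1.81% to 2.38% of the reads. The translation factor EEF1A1 was the most abundant gene in each library, with 1.59% to 3.96% of the reads.

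Transcripts of CPXM2 and of 3 fibrillar collagen genes were low in the cells. CPXM2 (ENSG00000121898, hg38 chromosome 10, 123706207 to 123940267, minus strand) had 0 reads in 8 libraries and 1 read in R213A 3, or 0.0112 FPKM. The related carboxypeptidase gene CPXM1 had 0 reads in all 9 libraries. COL1A1 reached at most 0.0558 FPKM, COL1A2 had 2 reads in control 3 and 0 in the other libraries, and COL3A1 lay between 0 and 0.828 FPKM. The carboxypeptidase gene CPE was expressed at 5.26 ± 2.29 FPKM on control, 4.35 ± 1.77 on wild-type and 3.21 ± 2.23 on R213A matrix (SD, n = 3 each). R213A has 2 libraries in the 4-library table and the other groups have 1, so means of R213A also carry the difference between the tables. These values place no CPXM2 transcript above the floor in the groups exposed to CPXM2 matrix, so the sequenced RNA cannot check which matrix a library had met.

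Receptors for collagen were present in all groups. DDR1, a receptor tyrosine kinase that binds collagen, was at 4.17 ± 1.21, 3.97 ± 0.329 and 3.98 ± 0.203 FPKM on control, wild-type and R213A matrix (SD, n = 3 each). ITGB1, the shared beta chain of the collagen-binding integrins, was at 207 ± 98.9, 165 ± 89.7 and 101 ± 101 FPKM. Its partner ITGA2 was at 6.48 ± 4.46, 6.70 ± 4.74 and 4.26 ± 6.55 FPKM. DDR2, the other discoidin receptor, stayed between 0.103 and 0.666 FPKM. The mesenchymal gene VIM was at 132 ± 62.9, 142 ± 61.3 and 139 ± 33.7 FPKM, and the E-cadherin gene CDH1 at 0 to 0.136 FPKM.

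Most markers of cells that could have been carried over with the matrix had a mean under 1 FPKM. Of 21 fibroblast markers 1 exceeded it, with a mean of 9.21 FPKM, and of 17 immune and 11 fat cell markers 0 did, with highest means of 0.280 and 0.736 FPKM. Of 27 genes of the classical pancreatic tumour subtype 1 was measured. These lists were therefore not tested. Of 13 endothelial markers 3 were measured, and they did not pass the list test in any comparison (camera adjusted p = 0.194, 0.147 and 0.647 for wild type against control, R213A against control and wild type against R213A).

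The deposited table separated the libraries more than the matrix did, except for control 1. Between a library of the 4-library table and a library of the 5-library table, 1663 to 5434 of the 11193 genes differed at least 2-fold. Within the 4-library table the 6 pairs differed in 387 to 2316 genes. Control 1 differed from R213A 3, wild type 1 and R213A 1 of its own table in 387, 1862 and 2316 genes. From control 3, wild type 2, wild type 3 and R213A 2 of the other table it differed in 1781, 1799, 1663 and 1794 genes, and from control 2 in 2273. In the 5-library table control 3, wild type 2, wild type 3 and R213A 2 were close to each other, with 41 to 66 genes per pair and correlations of 0.992 to 0.994 across genes. Control 2 differed from these 4 libraries in 376 to 416 genes. The first principal component held 77.2% of the variance and split the tables.

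**Figure D1:**
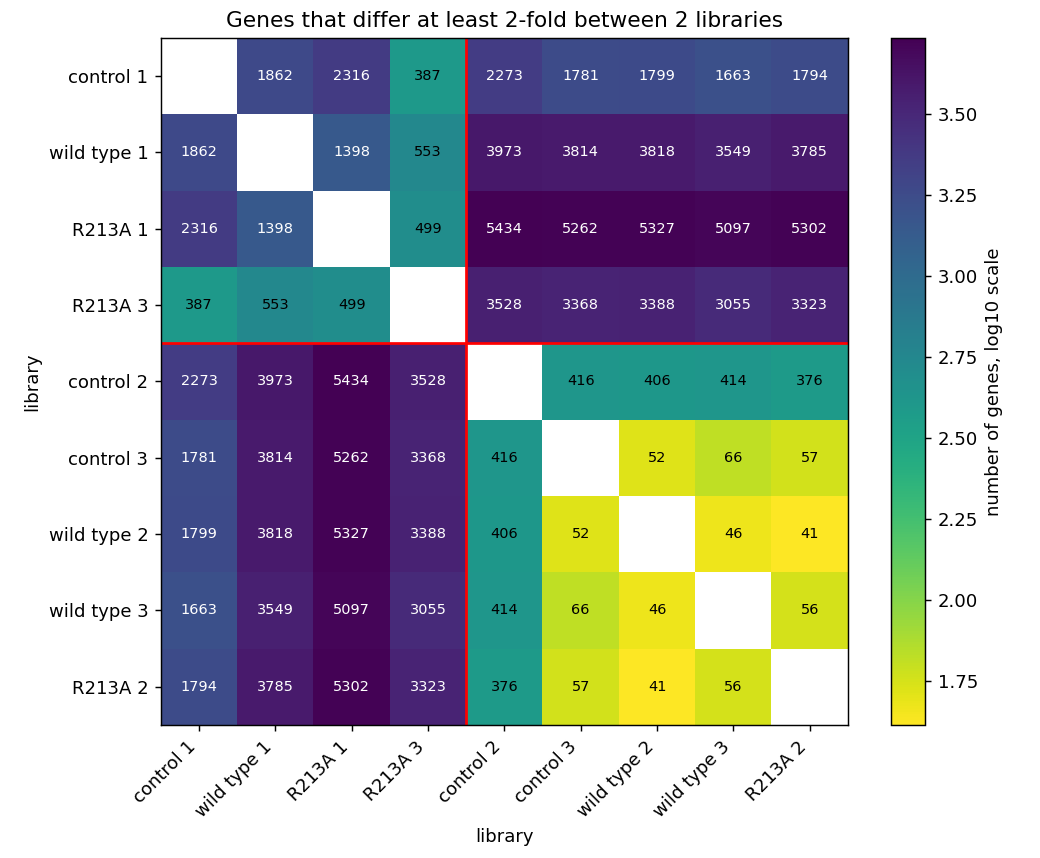
Number of genes, out of 11193, that differ at least 2-fold on the log2(FPKM + 1) scale between each pair of libraries, with the library names on both axes, the colour on a log10 scale and red lines between the 4-library and the 5-library table. The 4 closest libraries differ from each other in 41 to 66 genes, and pairs across the tables differ in 1663 to 5434 genes.

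The first comparison asked what wild-type CPXM2 matrix did relative to control matrix. Mitotic genes stood lower on wild-type matrix. Targets of the stress factor ATF4 and chaperones of the endoplasmic reticulum stood higher, but heat shock genes did not. The largest differences lay between wild type 1 and control 1. TOP2A, the topoisomerase of dividing cells, was at 6.52 FPKM in wild type 1 and 60.9 in control 1, but at 44.6 and 39.5 FPKM in wild type 2 and 3 against 56.6 and 44.3 in control 2 and 3. TRIB3, a target of the stress factor ATF4, was at 316 FPKM in wild type 1 and 11.6 in control 1, and at 60.1 and 67.8 FPKM in wild type 2 and 3 against 63.6 and 61.6 in control 2 and 3. Genes of cholesterol synthesis stood lower in both tables, in the 5-library table through control 2 alone, as with HMGCS1 at 166 ± 201 FPKM on control and 56.8 ± 45.9 on wild-type matrix (SD, n = 3 each).

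No single gene passed the threshold in this comparison. limma called 0 of 11193 genes, with 503 at an unadjusted p under 0.05 (252 higher and 251 lower) and a smallest adjusted p of 0.757, and limma-voom on recovered reads also called 0, with 537 unadjusted. Single libraries moved the unadjusted count, to 73 without wild type 1, 116 without control 1 and 1378 without control 3. The genes of smallest p with the same direction in both tables included the secreted protease inhibitor SLPI, 0.97 ± 0.25 higher on the log2 scale (SE, limma adjusted p = 0.757). SLPI was at 0.557 ± 0.305 FPKM on control and 2.11 ± 0.942 FPKM on wild-type matrix (SD, n = 3 each). The log2 difference was 0.68 for the synaptic vesicle gene SYP, 0.68 for the tubulin ligase gene TTLL1, 0.79 for BCAN, 0.77 for AIFM2, 1.05 for TRIM16 and 0.61 for BATF2. On the lower side it was -0.89 for ADAMTSL4, -0.55 for the thrombin receptor gene F2R, -0.81 for the perlecan gene HSPG2, -0.64 for GALNT11, -0.75 for RBM25 and -1.32 for HMGCS1. The 5-library part of several of these shrank without control 2, from 0.47 to 0.11 for TRIM16, from 0.54 to 0.14 for AIFM2, from 0.38 to 0.14 for BATF2, from 0.48 to 0.19 for BCAN and from 0.69 to 0.33 for SYP. On the lower side it went from -0.60 to -0.18 for ADAMTSL4, from -0.37 to -0.24 for F2R, from -0.49 to -0.19 for HSPG2, from -0.48 to -0.17 for GALNT11, from -0.44 to -0.08 for RBM25 and from -1.17 to -0.11 for HMGCS1.

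By gene list, camera called 15 of 38 lists in this comparison, 7 higher and 8 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.489. In each list 0 members passed adjusted over all genes and 0 adjusted over the list alone, and the smallest adjusted p of fry was 0.366 for its directional and 0.662 for its mixed form. The G2/M cell cycle genes had a median log2 difference of -0.68, with 25 of 25 members lower (camera adjusted p = 6.44e-09; adjusted p = 0.489 with an estimated correlation). Their median was -2.04 in the 4-library table and -0.03 in the 5-library table. Mitochondrial genome transcripts, which follow RNA quality, stood lower in the same 4-library table, with a median of -0.80 and 0 of 13 members higher, and at 0.22 in the 5-library table (camera adjusted p = 0.000657 in the 4-library table, where lone libraries are assumed to vary like the others). In the pooled fit they did not pass (camera adjusted p = 0.199; adjusted p = 0.690 with an estimated correlation), but without control 2 they passed as lower (median -0.45, camera adjusted p = 3.33e-05). TOP2A differed by -3.04 and -0.25 in these tables and the kinase gene CDK1 by -2.19 and -0.17. The S phase genes had medians of -1.49 and 0.22, with MCM6 at -1.37 and -0.10 and TYMS at -2.19 and 0.00 (pooled median -0.39, camera adjusted p = 0.00107; adjusted p = 0.619 with an estimated correlation). Without wild type 1 the fit also drew on R213A against control, through the table term. The G2/M call ended there (median -0.06, camera adjusted p = 0.144). The S phase genes turned to a median of 0.10 and passed as higher in that fit (camera adjusted p = 0.0391). They passed as higher in the 5-library table alone as well (camera adjusted p = 0.00728), where the median of 0.22 fell to 0.03 without control 2, and without control 1 they did not pass (adjusted p = 0.999).

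Among stress genes, 21 of 21 ATF4 targets lay higher in the pooled fit, with a median of 0.48, against 1.37 in the 4-library table and 0.01 in the 5-library table (camera adjusted p = 3.49e-07; adjusted p = 0.489 with an estimated correlation). TRIB3 differed by 4.65 and 0.03 in these tables, and CHAC1, which degrades glutathione, by 4.49 and 0.32. The chaperones of the endoplasmic reticulum had a median of 0.45, with 0.87 and 0.25 in the tables, and HSPA5 differed by 2.37 and 0.35 (camera adjusted p = 9.57e-08; adjusted p = 0.489 with an estimated correlation). The chaperones also passed as higher in the 5-library table alone, with 18 of 20 members higher (camera adjusted p = 0.000626), but there the median was -0.01 without control 2. The NF-kB and cytokine genes had a median of 0.49 (1.18 and 0.12 in the tables), including the chemokine gene CXCL1 at 3.82 and 0.76 and LCN2 at 5.47 and 0.47 (camera adjusted p = 2.19e-05; adjusted p = 0.489 with an estimated correlation). Without wild type 1 the ATF4, chaperone and NF-kB lists still passed as higher, at lower medians of 0.21, 0.18 and 0.10 (camera adjusted p = 0.0388, 0.00488 and 0.0279). NRF2 targets (median 0.29, with OSGIN1 at 1.06), lysosome and autophagy genes (0.22, with CTSD at 0.79), interferon response genes (0.18, with IFI35 at 0.52) and ribosomal protein genes (0.22, with RPL10 at 0.36) were also called higher. Their adjusted p with an estimated correlation was 0.489, 0.489, 0.489 and 0.690. Without wild type 1 none of these last 4 lists passed, with adjusted p = 0.0880, 0.0773, 0.0880 and 0.0880. The NRF2 call also ended without control 2 (adjusted p = 0.0606), and the interferon call held only without R213A 1, with adjusted p of 0.0517 to 0.150 without any other library. Further, without control 1 the ribosomal protein genes turned to a median of -0.11 and passed as lower (camera adjusted p = 0.0306). Heat shock genes went the other way from the ATF4 and chaperone lists in the 4-library table, with a median of -0.66 and 1 of 18 members higher. Their median was 0.15 in the 5-library table, and 0.06 there without control 2. In the pooled fit 12 of 18 members lay lower and the list did not pass (median -0.15, camera adjusted p = 0.194).

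Several lists of mechanical signalling were called lower on wild-type matrix. The YAP/TAZ targets, which respond to matrix stiffness and cell shape, had 17 of 18 members lower and a median of -0.47, with -1.07 in the 4-library and -0.04 in the 5-library table (camera adjusted p = 3.65e-05; adjusted p = 0.489 with an estimated correlation). CCN1 was at 852 ± 448 FPKM on control and 573 ± 438 on wild-type matrix (SD, n = 3 each), a log2 difference of -2.69 in the 4-library and -0.32 in the 5-library table. ANKRD1 differed by -2.10 and -0.11 and the receptor gene AXL by -0.86 and -0.39, whereas CCN2 was at 0.74 and -0.68. In the 5-library table these values rested on control 2, and without it CCN1, ANKRD1, AXL and CCN2 were at 0.05, 0.02, -0.01 and 0.10. The SRF/MRTF targets (median -0.24, with the adhesion protein gene VCL at -0.83) and the focal adhesion components (median -0.18, with ACTN4 at -0.52) were called too, with adjusted p = 0.514 and 0.489 with an estimated correlation. Both calls ended without control 2 (adjusted p = 0.613 and 0.115), and the focal adhesion call without wild type 3 (adjusted p = 0.0714).

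Cholesterol synthesis genes had 21 of 22 members lower and a median of -0.52, with -0.73 in the 4-library and -0.35 in the 5-library table (camera adjusted p = 9.57e-08; adjusted p = 0.489 with an estimated correlation). In the 5-library table this rested on control 2: without it the median was -0.03. HMGCS1 was at 394 FPKM in control 2 and at 89.8, 82.8 and 83.8 FPKM in control 3, wild type 2 and wild type 3. INSIG1, a sterol-sensing gene, was at 337 FPKM in control 2 and at 129, 125 and 127 FPKM in the same libraries. The fatty acid synthesis genes (median -0.29, with FASN at -1.05 and ACLY at -0.70) and the FOXO and PI3K-AKT feedback genes (median -0.24, with IRS2 at -0.53) were called lower as well, both with adjusted p = 0.489 with an estimated correlation. The fatty acid call ended without control 2 (adjusted p = 0.122) and the FOXO call without each of control 1 and 3, wild type 2 and 3 and R213A 2 and 3 (adjusted p = 0.265, 0.0798, 0.102, 0.127, 0.0531 and 0.0505). Collagen receptors and integrins (median -0.19, camera adjusted p = 0.194), basement membrane genes (median -0.28, adjusted p = 0.183) and mesenchymal genes (median -0.33, adjusted p = 0.213) did not pass. In the 5-library table alone the receptors and the basement membrane genes passed as lower (camera adjusted p = 0.0288 and 0.00728), with medians of -0.20 and -0.38 that were -0.05 and -0.10 without control 2.

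Across all genes, the fold changes of wild type against control in the 4-library table had a correlation of -0.02 with those in the 5-library table, or 0.11 without control 2, and 51.4% of the genes had the same sign. There were 1862 genes at least 2-fold apart in the 4-library table and 40 in the 5-library table, and 7 were so in both with the same direction.

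**Figure D2:**
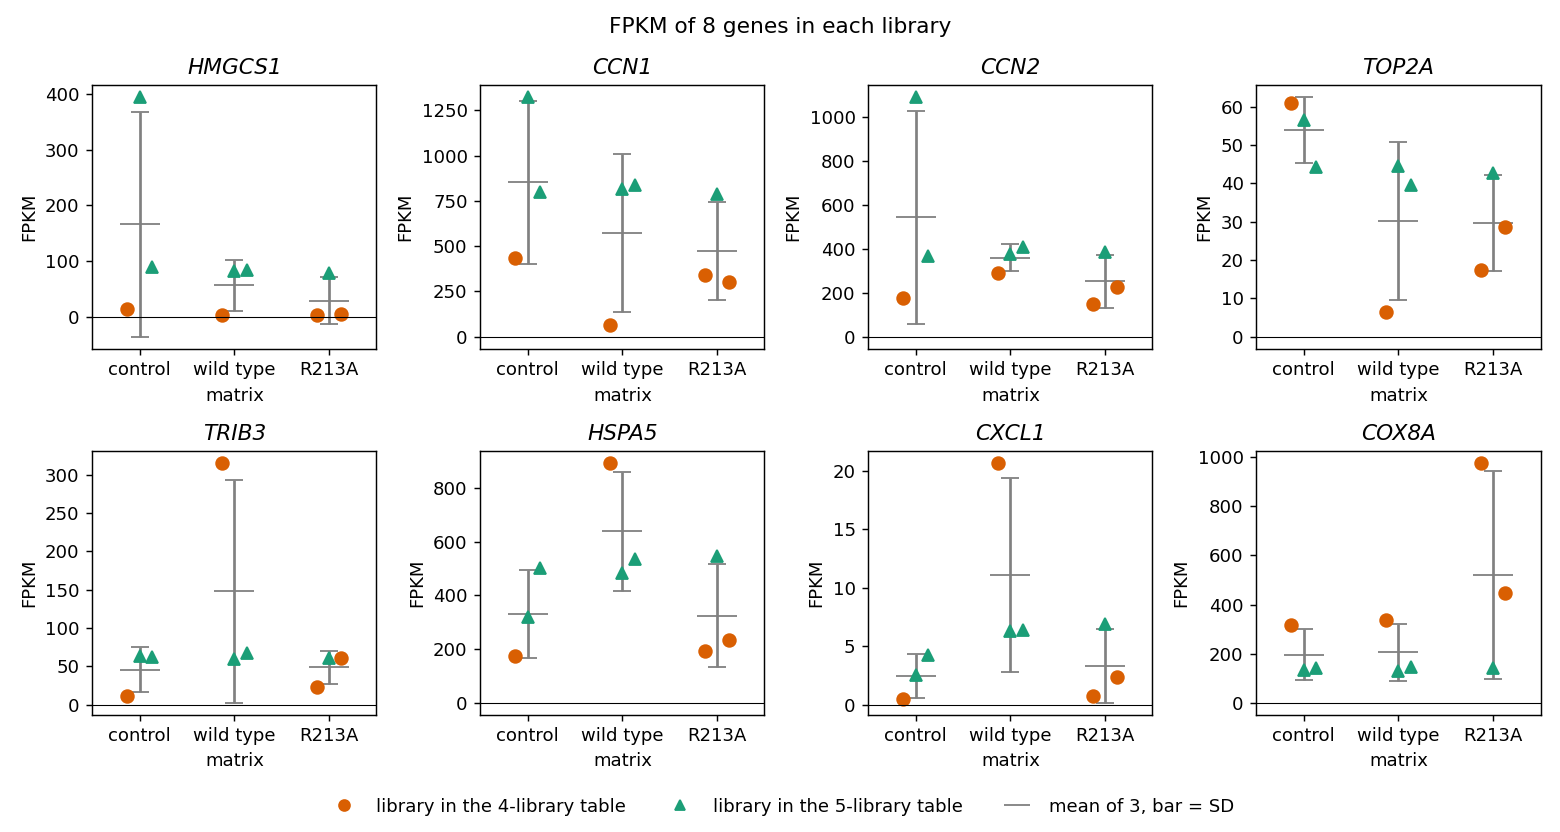
FPKM (linear vertical axis) of 8 genes on the 3 matrices (horizontal axis), with circles for libraries of the 4-library table, triangles for libraries of the 5-library table, and the group mean with its SD as the grey bar. TRIB3 reaches 316 FPKM in wild type 1 alone, HMGCS1 reaches 394 FPKM in control 2 alone, and COX8A reaches 977 FPKM in R213A 1.

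The second comparison asked what the R213A matrix did relative to control matrix. The ribosomal protein and oxidative phosphorylation lists stood higher on R213A matrix in the 4-library table and not in the 5-library table. Ribosomal protein genes were among the lists chosen to follow RNA quality. Gene length and GC content explained 37.5% and 31.0% of the variance of R213A 1 and 3 from the 4 closest libraries, and 13.8% for control 1. After correction for both, 4 of the 4 pooled list calls of this comparison were kept. Mitochondrial genome transcripts and the MYC and ribosome assembly genes did not rise in the 4-library table, with medians of -0.38 and -0.10. RPL13, a protein of the large ribosomal subunit, was at 1009 and 551 FPKM in R213A 1 and 3 against 287 in control 1, and at 243 FPKM in R213A 2 against 279 and 244 in control 2 and 3. COX8A, a subunit of cytochrome c oxidase, was at 977 and 445 FPKM in R213A 1 and 3 against 315 in control 1, and at 141 FPKM in R213A 2 against 133 and 141 in control 2 and 3. HMGCS1 was at 3.97 and 5.08 FPKM in R213A 1 and 3 against 13.7 in control 1, and at 78.5 FPKM in R213A 2 against 394 and 89.8 in control 2 and 3.

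limma called 0 of 11193 genes between R213A and control, with 341 at an unadjusted p under 0.05 (143 higher and 198 lower) and a smallest adjusted p of 0.690. limma-voom on recovered reads called 0, with 322 unadjusted. The unadjusted count went to 1123 without R213A 2, 1096 without control 3, 184 and 178 without wild type 2 and 3, 114 without control 1 and 99 without R213A 1. Among the genes of smallest p with the same direction in both tables, the log2 difference was 0.68 for the interferon-induced gene IFI6, 0.52 for CSRP2, 0.70 for SNCG, 0.73 for the sphingomyelinase gene SMPD2 and 0.74 for THAP7. It was -0.56 for the nuclear receptor gene NR2F2, -0.77 for ASAP2, -0.66 for the lipid kinase gene PIKFYVE, -0.75 for RBL2 and -1.29 for HMGCS1 (limma adjusted p = 0.690 for each of these 10 genes). Without control 2 the 5-library part lost its direction for ASAP2, from -0.29 to 0.00, and shrank from -0.32 to -0.09 for PIKFYVE, from -0.23 to -0.12 for NR2F2, from -0.23 to -0.15 for RBL2, from -1.25 to -0.19 for HMGCS1, from 0.28 to 0.10 for SNCG and from 0.34 to 0.17 for THAP7. ITGB1 differed by -0.80 on the log2 scale (95% interval -1.63 to 0.03), with -1.31 in the 4-library and -0.26 in the 5-library table, or -0.06 there without control 2.

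By gene list, camera called 4 of 38 lists for R213A against control, 2 higher and 2 lower, and 0 with an estimated correlation. The count moved to 11, 7, 8 and 7 without control 1, control 3, wild type 1 and R213A 1. In each list 0 members passed adjusted over all genes and 0 adjusted over the list alone, and the smallest adjusted p of fry was 0.693 for its directional and 0.777 for its mixed form. The ribosomal protein genes had 28 of 28 members higher in the pooled fit and a median of 0.40 (camera adjusted p = 3.95e-07; adjusted p = 0.766 with an estimated correlation). Their median was 1.02 in the 4-library and -0.14 in the 5-library table, with RPL13 at 1.38 and -0.10. In the 5-library table alone, where R213A 2 is the only R213A library and is assumed to vary like the others, they passed as lower (camera adjusted p = 0.00538), but the median was 0.02 without control 2. Without control 1 their pooled median was -0.06 (adjusted p = 0.297). The oxidative phosphorylation genes had medians of 0.39 in the pooled fit, 0.77 in the 4-library and -0.10 in the 5-library table, with NDUFS8 at 1.27 and -0.07 (camera adjusted p = 1.06e-05; adjusted p = 0.766 with an estimated correlation), and did not pass without control 1 (adjusted p = 0.105). Mitochondrial genome transcripts stood lower in the 4-library table, with a median of -0.38 and 3 of 13 members higher, and did not pass in the pooled fit (camera adjusted p = 0.0307 and 0.481).

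Cholesterol synthesis genes were called lower on R213A matrix, with a median of -0.20 and 16 of 22 members lower (camera adjusted p = 0.0267; adjusted p = 0.793 with an estimated correlation). CYP51A1, an enzyme of sterol synthesis, differed by -1.18 in the 4-library and -0.56 in the 5-library table. Without control 2 the median in the 5-library table went from -0.43 to -0.09 and the pooled call ended (adjusted p = 0.626), as it did without R213A 2 and R213A 3 (adjusted p = 0.778 and 0.0822). The FOXO and PI3K-AKT feedback genes had a median of -0.32, with IRS2 at -0.55 and the cyclin gene CCNG2 at -0.40 (camera adjusted p = 0.0106; adjusted p = 0.766 with an estimated correlation), and did not pass without control 1 (adjusted p = 0.105). YAP/TAZ targets (median -0.19, camera adjusted p = 0.104), ATF4 stress genes (median 0.24, adjusted p = 0.138) and G2/M genes (median 0.01, adjusted p = 0.951) did not pass in the pooled fit. In the 4-library table alone, with control 1 assumed to vary like the others, their medians were -0.50, 0.71 and -0.52 (camera adjusted p = 0.00138, 5.5e-07 and 0.0102), and in the 5-library table -0.02, -0.03 and 0.00. The fold changes of the tables had a correlation of -0.06, or 0.01 without control 2, and 940 genes in the 4-library and 59 in the 5-library table differed at least 2-fold, 11 of them in both with the same direction.

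The third comparison set wild-type against R213A matrix, which both contain CPXM2. Cell cycle and heat shock genes stood lower on wild-type matrix, and ATF4 stress, ER chaperone and cytokine genes higher, again through wild type 1. UBE2C, which drives exit from mitosis, was at 74.7 FPKM in wild type 1 against 307 and 225 in R213A 1 and 3, and at 67.9 and 67.2 FPKM in wild type 2 and 3 against 66.4 in R213A 2. PPP1R15A, a phosphatase subunit induced by stress, was at 174 FPKM in wild type 1 against 38.1 and 33.4 in R213A 1 and 3, and at 45.6 and 51.2 FPKM in wild type 2 and 3 against 49.2 in R213A 2.

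limma called 0 of 11193 genes between the CPXM2 matrices, with 117 at an unadjusted p under 0.05 (44 higher and 73 lower) and a smallest adjusted p of 0.996, and limma-voom called 0, with 119 unadjusted. The unadjusted count went to 774 without R213A 2, 333 without control 1, 196 without wild type 2, 41 without R213A 1 and 39 without wild type 1. The log2 difference was 0.86 for the tight junction gene CLDN23, 0.51 for the vesicle transport gene BET1, 0.69 for SRXN1 and 0.89 for the chaperone gene CLGN. It was -0.69 for the meiotic recombination gene MND1, -0.98 for the kinetochore gene CENPW and -0.94 for the replication gene GINS2 (limma adjusted p = 0.996 for each of these 7 genes). A shared direction in both tables was a condition for naming these genes, and over all genes 45.6% had the same sign. CLDN23 was at 1.26 and 0.46 and GINS2 at -1.86 and -0.15 in the 4-library and 5-library table.

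By gene list, camera called 14 of 38 lists between the CPXM2 matrices, 6 higher and 8 lower on wild-type matrix, and 0 with an estimated correlation. Without wild type 1 camera called 3 lists. In each list 0 members passed adjusted over all genes and 0 adjusted over the list alone, and the smallest adjusted p of fry was 0.703 for its directional and 0.855 for its mixed form. The G2/M genes had 25 of 25 members lower and a median of -0.72, with -1.66 in the 4-library and 0.03 in the 5-library table (camera adjusted p = 4.47e-13; adjusted p = 0.540 with an estimated correlation). UBE2C differed by -1.80 and 0.03, AURKB by -2.38 and 0.09 and PLK1 by -1.87 and 0.01. Mitochondrial genome transcripts stood lower in the 4-library table (median -0.41, 2 of 13 members higher, camera adjusted p = 0.0396) and at 0.08 in the 5-library table, with 13 of 13 members higher, and did not pass in the pooled fit (adjusted p = 0.645). The S phase genes (median -0.57, with MCM5 at -0.67 and CDC45 at -0.71) had medians of -1.42 and 0.01 in the tables. The ER chaperones had 20 of 20 members higher and a median of 0.37, with 0.74 and 0.00 in the tables, including HYOU1 at 1.68 and -0.02 and DNAJB9 at 1.96 and 0.03. NF-kB and cytokine genes (median 0.30), immediate early genes (0.35, with EGR1 at 1.22 and ATF3 at 0.61), ATF4 stress genes (0.25), NRF2 targets (0.18) and lysosome and autophagy genes (0.10) were called higher. Oxidative phosphorylation genes (median -0.34, with ATP5MC1 at -0.64), heat shock genes (-0.24, with HSPE1 at -0.64), cholesterol synthesis genes (-0.24), SRF/MRTF targets (-0.26, with TAGLN2 at -0.54), ribosomal protein genes (-0.18) and YAP/TAZ targets (-0.19) were called lower. For these 14 lists the adjusted p with an estimated correlation ran from 0.540 to 0.719.

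Within the 5-library table alone, camera called 0 of 38 lists between wild type 2 and 3 and R213A 2, a lone library assumed to vary like the others. Without wild type 1, only the oxidative phosphorylation and ribosomal protein genes of the 14 lists stayed lower, with medians of -0.27 and -0.34, and the G2/M, S phase, YAP/TAZ and ATF4 medians changed sign, to 0.11, 0.19, 0.18 and -0.19. Without R213A 1 the ATF4 and ribosomal protein lists did not pass (adjusted p = 0.142 and 0.618), and without control 1 or wild type 2 the ribosomal protein list did not (adjusted p = 0.428 and 0.174). The YAP/TAZ and lysosome lists ended without R213A 2 (adjusted p = 0.284 and 0.122) and without R213A 3 (adjusted p = 0.199 and 0.137), and the NRF2 list without R213A 2 (adjusted p = 0.103). The fold changes of the tables had a correlation of -0.06, and 3 genes differed at least 2-fold in both with the same direction.

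**Figure D3:**
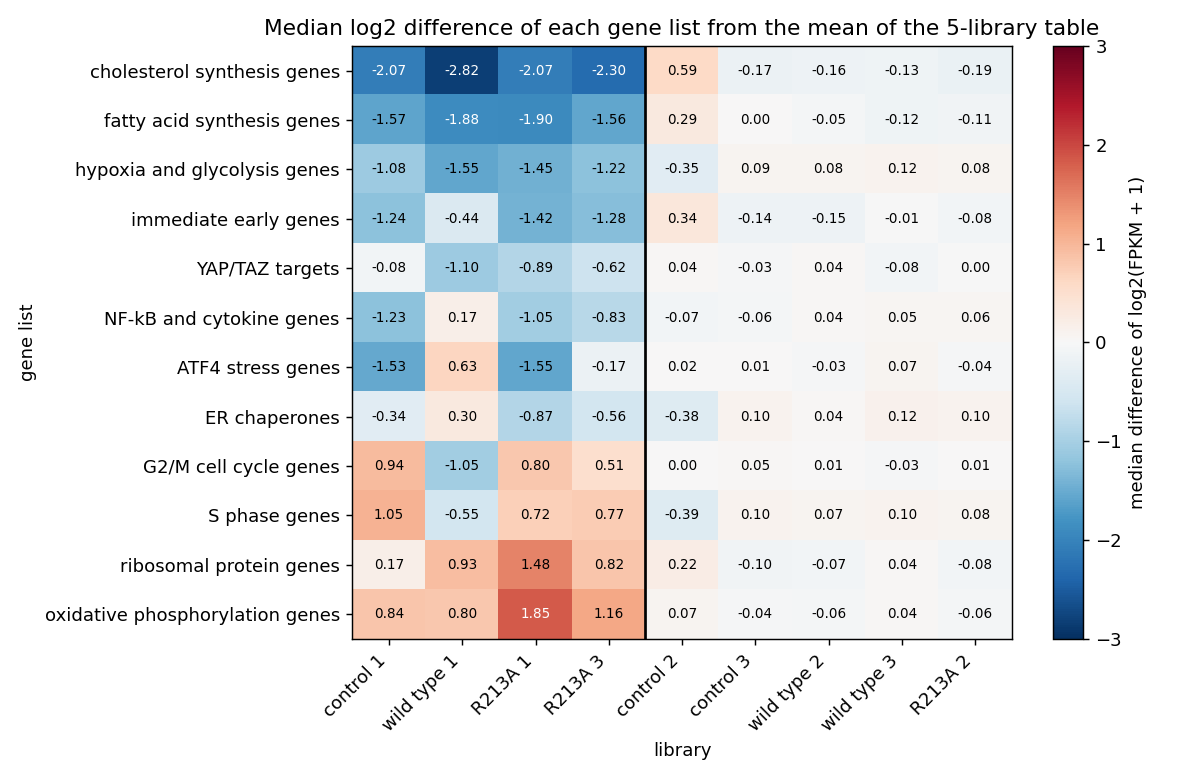
Median difference in log2(FPKM + 1) of 12 gene lists (vertical axis) in each of the 9 libraries (horizontal axis) from the mean of the 5-library table, with a black line between the tables. The G2/M list is at -1.05 in wild type 1 and at 0.94 in control 1, and the ATF4 list is at 0.63 and -1.53 in these libraries. Control 3, wild type 2, wild type 3 and R213A 2 stay close to 0 in each list, in part by construction, since they belong to the mean used as reference.

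The fold changes of both CPXM2 matrices against the same control libraries were compared across genes. Their Pearson correlation was 0.641 and the Spearman correlation 0.667 over 11193 genes, which are not independent replicates. In 100 simulations of unchanged groups the correlation averaged 0.480 and reached at most 0.506. There each library, controls included, was drawn anew, with a spread equal across libraries and independent between genes. The covariance was 0.0593 against a simulated mean of 0.0305, a difference of 0.0288. The measured controls were unequal and genes of a list moved together, which the simulations left out. Part or all of the excess may therefore come from the shared controls, which were too few to split, so it does not show a shared response. Without the table term the covariance lay below its simulated mean, with a difference of -0.00794. The comparisons shared 0 called genes. HMGCS1 was among the genes lower in both, with a log2 difference of -1.32 on wild-type and -1.29 on R213A matrix. In the 5-library table these differences were -1.17 and -1.25, and -0.11 and -0.19 without the shared control 2.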

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

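The settings with voom, the length and GC correction, the 5-library table without control 2, and the list tests within tables, without the trend or with library weights were chosen only after the result was seen. The count of 0 genes in all 3 comparisons kept under each leave-one-out fit (0 to 0 genes), both other pseudocounts, the stricter filter, both scalings, no table term, both replicate blocks, only the groups compared, the 5-library table alone, no trend, voom and the length and GC correction. Without a filter 1 gene each was called against control for wild type and R213A. The 4-library table alone, with 1 residual degree of freedom, called 775 genes for wild type against control, 184 for R213A against control and 327 for wild type against R213A, and these counts rest on the spread between R213A 1 and 3, with the lone libraries assumed to vary alike. Library weights called 6 and 7 genes against control, and the 5-library table without control 2 called 14 and 16, which rest on the spread between wild type 2 and 3, with 1 control and 1 R213A library assumed to vary alike.

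Of the list counts (15, 4 and 14), those with an estimated correlation were 0, 0 and 0. With library weights they were 9, 8 and 3, which kept 7, 2 and 1 of these calls, and in the 5-library table without control 2 they were 5, 5 and 3, which kept 3, 0 and 0. For R213A against control 3 of the 4 calls were kept with a pseudocount of 0.1, and 8 lists passed with only the groups compared, 11 in the 5-library table (1 of the 4 calls kept and 1 turned), 8 in the 4-library table and 9 after the length and GC correction. For wild type against control the 5-library table kept 6 of the 15 calls and turned 1, and for wild type against R213A 0 passed there. Leaving out each library gave 13 to 18 lists for wild type against control, of which 9 of the 15 calls were kept without wild type 1, with 1 opposite call, 10 without control 2 and 11 without control 1, with 1 opposite call. It gave 3 to 11 for R213A against control (11 without control 1) and 3 to 16 for wild type against R213A (3 without wild type 1). The cause was not tested.

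Whether the replicate numbers pair the libraries could not be told from deviations from the group means, which still held the difference between the tables. These deviations correlated at 0.335 to 0.843 within numbers 1 and 2, where libraries of a number share a table. Control 3 and wild type 3, which share a table, correlated at 0.566. R213A 3, in the other table, was at -0.651 and -0.702 with them, so the signs follow the tables. The replicate block called 0 genes in each comparison and 12, 6 and 11 lists, but at an unadjusted p under 0.05 it had 183, 2478 and 1001 genes, against 503, 341 and 117. Without the table term there were 66, 79 and 56. The shared correlation of 0.641 went to 0.631 with a pseudocount of 0.1, 0.679 with quantile scaling and 0.541 without the table term. Depth limits CPXM2 and COL1A2, whose 1 and 2 reads lie under the limit of 3 reads. It also limits single values of other named genes. Among them, SLPI had 2 reads in control 2, LCN2 had 1 read in control 1 and CYP51A1 had 2 reads in R213A 1.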

Other observations

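The tests of other cell kinds, of a response in each culture, of near-identical libraries and of other splits of the samples were chosen only after the result was seen. The difference between the deposited tables included many genes of lipid, sugar and energy metabolism. With the group in the model, limma called 6674 of 11193 genes between the tables, 2957 higher and 3717 lower in the 4-library table. Cholesterol synthesis genes stood lower there by a median log2 of -2.31, with 18 of 22 members passing, and fatty acid synthesis genes by -1.51, with 10 of 12 passing. SCD, the desaturase of fatty acids, was at 68.8 to 156 FPKM in the 4-library table and at 2275 to 3766 FPKM in the 5-library table. Hypoxia and glycolysis genes were lower by a median of -1.43 with 20 of 25 members passing, among them LDHA at -1.48 and PGK1 at -1.06, and immediate early genes by -1.26 with 12 of 18. Oxidative phosphorylation genes were higher by a median of 1.03 with 23 of 25 passing, ribosomal protein genes by 0.74 with 19 of 28 and MYC and ribosome assembly genes by 0.71 with 16 of 25. With an estimated correlation the smallest adjusted p of these lists was 0.563. Control libraries lie in both tables, and for the cholesterol synthesis genes control 1 also stood low, at -2.07 from the mean of the 5-library table. For the ribosomal protein genes the controls did not show the difference. Control 1 was at 0.17 there, between control 3 at -0.10 and control 2 at 0.22. Wild type 1, R213A 1 and R213A 3 were at 0.93, 1.48 and 0.82, so for this list table and matrix cannot be told apart. SCD, LDHA and PGK1 were named after their values were seen.

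The first pattern weighed was this separation of the tables. Cells of a clearly distinct kind are argued against, since 0 genes above 20 FPKM in any library of the 4-library table were under 0.5 FPKM throughout the 5-library table. This rule cannot see a closely related kind or a small share of other cells, which stay open. Gene length and GC content explained 33.8% of the variance of the difference, and correcting for them left 1834 of 3229 genes at least 2-fold apart, so a bias of this kind cannot be told apart from other causes for the table difference as a whole. For the cholesterol synthesis genes it is argued against, since their median was -2.35 before and -2.41 after the correction (95% interval -2.97 to -1.35, from a bootstrap over genes). A different culture state or handling day of the tables, such as cell density or age of the medium, remains a hypothesis that no label allows to be tested, and no biological explanation was tested since the tables are not groups of the study.

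The second pattern was the high level of ATF4 stress and ER chaperone genes in wild type 1 relative to control 1. From the mean of the 5-library table, the ATF4 list was at 0.63 in wild type 1, -1.53 in control 1 and -1.55 in R213A 1. The chaperones were at 0.30, -0.34 and -0.87 in these libraries. The difference therefore held a low level in control 1 as well as a high level in wild type 1. Over 41 genes the median log2 difference from control 1 was 1.06, and it stayed at 1.06 after the correction for length and GC content (interval 0.79 to 1.42), which argues against such a bias. A response to the wild-type matrix of like size in each culture is argued against for wild type 2 and 3. The median in the 5-library table was 0.20 (interval 0.06 to 0.26), and -0.01 without control 2. Both intervals come from a bootstrap over the 41 genes and do not measure the spread between cultures. Over the 41 genes R213A 3 was 0.42 and R213A 1 was 0.10 above control 1. The lists parted in R213A 3. From the mean of the 5-library table, its ATF4 list was at -0.17, above control 1 at -1.53. Its chaperones were at -0.56, below control 1 at -0.34. A higher ATF4 level than in control 1 was therefore not limited to wild type 1. A response limited to one culture, or stress of that culture unrelated to the matrix, stays open. How much of the difference belongs to wild type 1 and how much to control 1 cannot be told either. The 4-library table holds a single wild-type and a single control library.

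The third pattern was the closeness of control 3, wild type 2, wild type 3 and R213A 2, which come from all 3 groups. A single library under 4 names is argued against, since the mean chi-square per gene between pairs was 2.79 or more, where 1 is expected of reads drawn from the same library. The pair of wild-type libraries differed by 5.44 and the 6 pairs ranged from 2.79 to 5.93, where 3 of the 5 pairs of different groups were closer than the wild-type pair, and by genes at least 2-fold apart 1 was (41 against 46 genes). The 3 closer pairs were those without wild type 3, at 2.79, 3.05 and 4.66. Among the pairs of wild type 3, wild type 2 was the nearest, at 5.44 against 5.88 for control 3 and 5.93 for R213A 2. By genes at least 2-fold apart it was 46 against 66 and 56. The comparison thus reflects wild type 3 as a library and cannot place matrix effects below the spread between libraries. Cultures or RNA handled together remain a hypothesis, found and tested on the same data. Swapped labels among these libraries were not tested and stay open, and would change what the group differences within the 5-library table mean.

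The split of 6 libraries into groups of 3 can be made in 10 ways, too few for a share under 0.05. For each of the 3 comparisons the real split called 0 genes and the highest of the other splits called 0. With a real count of 0, all 10 of 10 splits are at least as large by construction, so this count does not test the grouping. At an unadjusted p under 0.05 the real splits gave 503, 341 and 117 genes, and the highest others gave 724, 1612 and 2416. The split with 2416 genes put wild type 1, R213A 1 and R213A 3 on the same side, which follows the tables. The table term stayed in that fit and was then set by the controls alone, so the count does not measure the separation of the tables. Its cause was not tested.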
